A study of Rattus norvegicus with 48 samples.

How the data were processed

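RNA bound to tagged ribosomes was measured by sequencing in the nucleus accumbens of adult male and female rats. Per the labels, translating ribosome affinity purification (TRAP) was carried out on 48 brains with antibodies to green fluorescent protein, so that the RNA came mainly from medium spiny neurons of one type. D1:Cre rats mark neurons of the dopamine D1 receptor pathway, and A2a:Cre rats mark those of the adenosine A2a and dopamine D2 receptor pathway. The animals took cocaine or saline by self-administration over 10 sessions, and they were killed on withdrawal day 1 or 40. The 6 groups held 8 libraries each, named by the sample titles. Sex is not given for each library in the sources used here, and no saline group was taken at day 40. The input RNA saved before the pull-down was not analysed here.

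The deposited table held whole-number counts of reads per gene, not normalized, for 32883 Ensembl gene identifiers in the 48 libraries. Per the submitters' processing notes, bcl2fastq, Trimmomatic, STAR and SAMtools were used with the Rnor_6.0 genome; their versions and settings, the counting program, the annotation release and the strand setting are not given in the sources used here. Gene names were those that the deposited table itself pairs with its identifiers, and 12500 identifiers had none. The reference table at hand was of another assembly, GRCr8, so no coordinates are printed. All 32883 entries named a gene, so none was left out of the library totals. Without a stated strand setting, reads of overlapping or antisense genes cannot be told apart, and counts of near-identical copies such as histone genes, ribosomal protein genes, Rpph1 and class I or II histocompatibility genes are uncertain.

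Library totals ran from 5.3 to 55.1 M counts, and 47 of the 48 libraries lay above 24 M. In those a gene at 1 CPM, the count scaled to the library total, therefore rested on at least 24 counts. Replicates were taken to be separate animals, because the labels speak of 48 brains. No pair of libraries within a group was a duplicate. The lowest chi-square per gene among the 168 within-group pairs was 10.3, and 0 of these pairs held identical counts.

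Groups were compared with edgeR 4.0.16 in R 4.3.3. Genes were kept by its filter on expression with a minimum count of 10, which left 15580 genes. Library sizes were scaled by trimmed means of M values (TMM). One quasi-likelihood model with robust dispersions and 1 term per group was fitted to all 48 libraries, so that the groups shared an estimate of the spread. Each contrast was tested with Benjamini-Hochberg adjustment over all 15580 genes at 0.05. Positive log2 changes mean higher in the group named first. Errors on log2 changes are standard errors (SE) implied by the quasi-likelihood F statistic, the size of the change divided by the square root of F. CPM values are group means ± SD over 8 libraries on TMM-scaled totals. The contrasts were cocaine day 1 against saline, cocaine day 40 against cocaine day 1 and cocaine day 40 against saline in each cell type, D1 against A2a in saline animals, and the interactions of cell type with cocaine and with withdrawal day.

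The gene lists, contrasts, main tests, named-gene rule and most alternatives were fixed before the data were examined. The 50 lists covered markers of medium spiny neurons and other cell types, activity-response, receptor, channel, signalling, stress, immune, metabolic and structural genes, and 48 of them had at least 5 tested members. The list of mitochondrially encoded genes had 0 members, because its pattern required a prefix that the deposited table does not use, and was not tested; those genes were looked up by name after the results were seen. They were tested with limma 3.58.1 camera at a preset correlation between genes of 0.01, two-sided, adjusted over the lists within a contrast, and again with the correlation estimated for each list. Members past 0.05 were counted over all genes and adjusted over the list alone. In each cocaine contrast, the named genes were the 6 with the largest rise and the 6 with the largest fall among called genes with a name and a mean log2 CPM of at least 3, the 4 with the smallest p in each direction, and up to 3 called members of each list, together with a panel of Fos, Arc, Bdnf, glutamate and dopamine receptor and neuropeptide genes. Where fewer than 10 genes passed, those with the next smallest p were named as not passing. For D1 against A2a, all tested medium spiny neuron markers were taken. Exceptions are given as chosen after their values were seen.

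The steps were tested on simulated counts made from the real means and library sizes. The changed genes were drawn only from those with a mean above 1 CPM. Counts were drawn independently, with no difference by animal set, processing order or sex, so the simulation does not cover these. In a simulated D1 day 40 against saline contrast of 15426 genes, edgeR recovered 48 of 67 genes changed 1.5-fold (71.6%), 59 of 67 changed 2-fold (88.1%) and 66 of 66 changed 4-fold (100%), with 7 unchanged genes called. It called 0 genes in a simulated contrast with no change.

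The alternatives were DESeq2 1.42.0, limma-voom with quality weights, other scaling factors, no filter or a stricter one on low counts, an adjusted p of 0.1, models of only the groups compared or of one cell type, and terms for the replicate number, the processing order, the middle number of the sample description (day 1 groups only), a score of non-neuronal markers or 5 surrogate variables from sva 3.50.0. The processing order was taken to be the first number of the sample description, cut into blocks of 6. Each library was also left out in turn. After the data had been seen, 3 further settings were added: without 3 libraries low in immune transcripts, without these and the library of lowest total, and with the interferon list score as a covariate. The list tests were then also repeated with each library of the groups compared left out.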

Results

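Ribosome-bound RNA was collected from nucleus accumbens punches of rats that had taken cocaine or saline by self-administration, and the series title ties the work to the growth of cocaine craving during withdrawal. The nucleus accumbens is the ventral part of the striatum, and nearly all of its projection neurons are medium spiny neurons of the D1 or the D2/A2a kind. Each of the 2 genetically marked neuron types was sampled in 8 saline animals at withdrawal day 1, 8 cocaine animals at day 1 and 8 cocaine animals at day 40, which gave 48 libraries. Median totals per group lay between 35.2 M counts (D1 saline) and 39.1 M (D1 cocaine day 1 and A2a cocaine day 40). The extremes were A2a cocaine day 1 replicate 7 with 5.3 M and A2a cocaine day 40 replicate 1 with 55.1 M. The first principal component of log2 CPM held 13.1% of the variance and the second held 9.2%. On the second, A2a cocaine day 1 replicate 7 stood apart at 111.4, while the next highest library scored 27.5. The middle number of the sample description was 85 in all D1 day 40 libraries and 88 in all A2a day 40 libraries, while the day 1 groups carried 89, 91 and 92. Withdrawal day and this number cannot be told apart within either neuron type.

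The first comparison asked how the neuron types differed in saline animals. In D1 libraries Pdyn, which encodes the opioid peptide precursor prodynorphin, averaged 1109 ± 135 CPM (SD, n = 8) against 173 ± 36.2 in A2a libraries. Drd1, the dopamine D1 receptor gene, stood at 171 ± 37.1 against 42.5 ± 7.08 CPM. Penk, the enkephalin precursor gene, averaged 937 ± 172 CPM in D1 and 8402 ± 1041 CPM in A2a libraries, and Drd2, the dopamine D2 receptor gene, 91.4 ± 18.2 and 628 ± 37.7 CPM. Adora2a, the adenosine A2a receptor gene, was at 214 ± 42.6 CPM in D1 and 834 ± 58.7 CPM in A2a libraries. For each of these 5 genes all 8 libraries of one type lay beyond all 8 of the other.

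**Figure D1:**
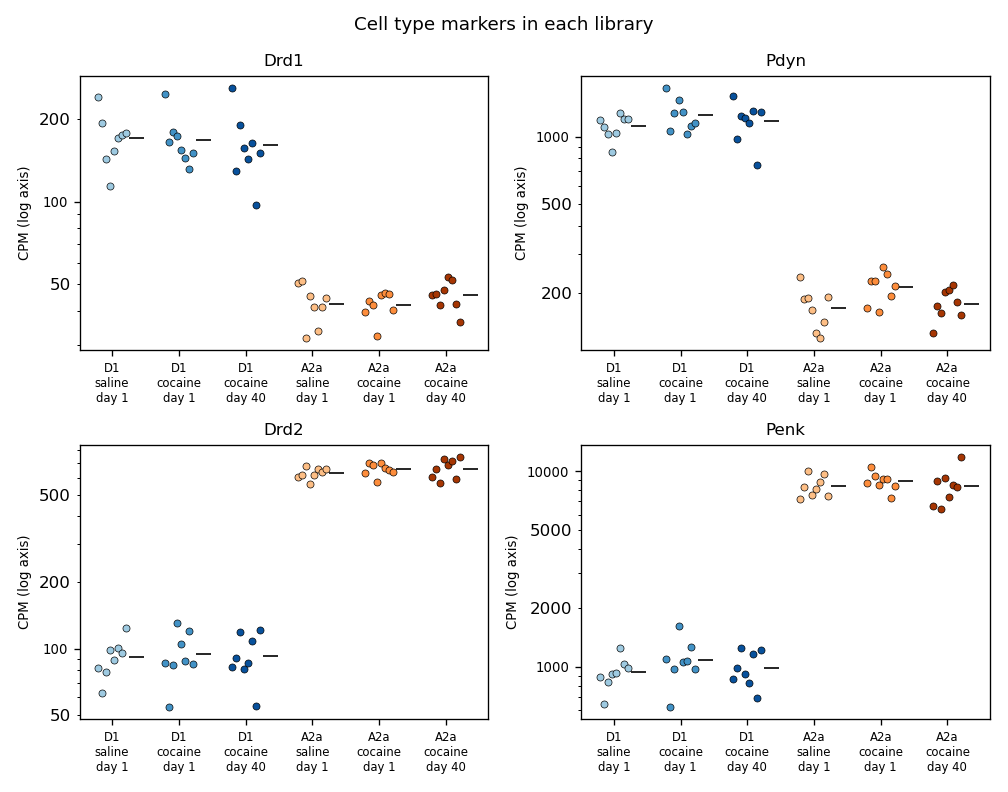
CPM of marker genes of the D1 and A2a neuron types in each of the 48 libraries, by group, on log axes, with 1 point per library and a tick at each group mean. Penk averaged 8402 CPM in A2a and 937 CPM in D1 saline libraries.

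Among 8 D1 markers 7 were higher in D1 libraries, with a median log2 difference of 2.16 over the list (limma camera adjusted p = 5.02e-40). They included Pdyn (2.68 ± 0.13, SE), Isl1, a transcription factor of striatonigral neurons (2.49 ± 0.11), Chrm4, the muscarinic M4 receptor gene (2.23 ± 0.10), and Drd1 (2.01 ± 0.14). Eya1, a transcriptional coactivator gene read at 0.392 ± 0.101 CPM, did not pass (0.053 ± 0.45, edgeR adjusted p = 0.974). All 8 D2/A2a markers were lower in D1 libraries, with a list median of -2.17 (limma camera adjusted p = 1.52e-37). Penk differed by -3.17 ± 0.14, Drd2 by -2.78 ± 0.13, the orphan receptor gene Gpr6 by -2.76 ± 0.12 and Adora2a by -1.96 ± 0.15. Both list calls held with an estimated correlation (limma camera adjusted p = 2.46e-08 and 3.01e-08).

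Of 14 genes expressed in both kinds of medium spiny neuron, 8 were lower in D1 libraries, or 10 adjusted over the list alone. Among them, Rasd2, a small GTPase gene, differed by -0.78 ± 0.15. Ppp1r1b, the DARPP-32 gene, did not pass (-0.18 ± 0.11, edgeR adjusted p = 0.373). The list fell, with a median of -0.27 (limma camera adjusted p = 3.01e-08, and adjusted p = 0.31 with an estimated correlation). Of 9 interneuron markers, 4 were higher in D1 libraries and 1 lower, or 4 and 2 adjusted over the list alone. Sst, which encodes somatostatin, differed by 2.09, and Lhx6, a transcription factor of interneurons from the medial ganglionic eminence, by 1.99 (edgeR adjusted p = 4.14e-15 and 1.50e-05). Th, the tyrosine hydroxylase gene, differed by -1.46 (edgeR adjusted p = 0.0158). The call on this list held with an estimated correlation (limma camera adjusted p = 0.000962 preset and 0.0145 estimated). The list of opioid and other neuropeptide genes also kept its call (limma camera adjusted p = 0.0194 preset and 0.025 estimated), with 7 of 18 members higher and 3 lower, or 8 and 3 adjusted over the list alone. They included Pnoc, the nociceptin precursor gene (2.52 ± 0.27), and Oprk1, the kappa opioid receptor gene (0.88), among those higher, and Oprd1, the delta opioid receptor gene (-2.0), among those lower. Over all 15580 genes, edgeR called 642 higher and 624 lower in D1 libraries, 1266 in total, and no single left-out library moved this count by over 1.5 times.

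The next question was what differed in D1 neurons 1 day after the last cocaine session. No gene passed. The activity marker Fos stood at 8.87 ± 3.57 CPM after cocaine and 9.40 ± 2.87 CPM after saline (SD, n = 8 each), Pdyn at 1252 ± 211 and 1109 ± 135 CPM, and Drd1 at 168 ± 35.5 and 171 ± 37.1 CPM. Gria1, an AMPA glutamate receptor subunit gene, differed by 0.011 ± 0.12 on the log2 scale (SE). Mmp9, which encodes an extracellular protease, had one of the smallest p values, with 4.37 ± 1.06 against 2.21 ± 0.643 CPM, a log2 difference of 0.98 ± 0.28, and 7 of 8 cocaine libraries above every saline library (edgeR adjusted p = 1.00). Pim3, a protein kinase gene, was at 45.1 ± 2.42 against 39.1 ± 2.90 CPM, with all 8 cocaine libraries above all 8 saline libraries (edgeR adjusted p = 1.00). Lins1 stood at 5.18 ± 0.795 against 7.09 ± 0.912 CPM, and the transporter gene Slc7a4 at 59.5 ± 7.33 against 49.0 ± 5.25 CPM.

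Over all genes edgeR called 0 (smallest adjusted p = 0.518), as did DESeq2 and limma-voom, and leaving out any library left the count at 0. At unadjusted p under 0.05 there were 363 genes by edgeR, 435 by DESeq2 and 961 by limma-voom, where chance alone would give 779. Among the lists, nuclear-encoded respiratory chain genes rose slightly, with 64 of 70 members above 0 and a median of 0.058 (limma camera adjusted p = 2.82e-08, and adjusted p = 0.977 with an estimated correlation). Astrocyte markers had 10 of 10 members above 0 with a median of 0.13 (limma camera adjusted p = 0.00642), and cholesterol synthesis genes had 18 of 20 above 0 with a median of 0.074 (limma camera adjusted p = 0.00824). No list in this comparison kept its call (adjusted p = 0.977 with an estimated correlation for each). At the preset correlation the astrocyte call was also lost without D1 cocaine replicate 4 or 7 or D1 saline replicate 1 or 2 (limma camera adjusted p = 0.0608, 0.0664, 0.121 and 0.154), with a median of 0.069 without the last and of 0.22 without saline replicate 4. The cholesterol call was lost without cocaine replicate 2 (median 0.026, limma camera adjusted p = 0.397). The counts of members past 0.05 for these 3 lists were 0 over all genes and 0 adjusted over the list alone.

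In A2a neurons the same comparison at day 1 gave 11 called genes, all higher after cocaine, and 3 of them had a name. Rpph1, the RNA component of ribonuclease P, averaged 34.3 ± 95.5 CPM after cocaine and 0.613 ± 0.216 CPM after saline (SD, n = 8 each), with 270.8 CPM in cocaine replicate 7 (log2 5.73 ± 1.10, edgeR adjusted p = 0.0145). Cds2, a phospholipid synthesis gene, averaged 7.14 ± 15.5 and 1.18 ± 0.362 CPM, with 45.4 CPM in replicate 7 (2.44 ± 0.51, edgeR adjusted p = 0.0292). Fos averaged 13.4 ± 9.25 CPM after cocaine and 7.22 ± 2.68 CPM after saline, a log2 difference of 0.91 ± 0.32 that did not pass (edgeR adjusted p = 0.573). Cocaine replicate 4 stood apart at 34.1 CPM, and the group medians were 11.2 and 6.80 CPM. Arc, an activity-regulated synaptic gene, stood at 86.7 ± 34.0 and 64.2 ± 16.2 CPM (0.44 ± 0.26, edgeR adjusted p = 0.876), and Pdyn differed by 0.30 ± 0.12 (edgeR adjusted p = 0.701).

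Replicate 7 was the library of 5.3 M counts. Without it 0 genes were called and Rpph1 and Cds2 differed by -0.12 and 0.51. The count was 17 without cocaine replicate 6, and 7, 6, 6, 0, 0 and 3 without saline replicates 1, 2, 3, 4, 5 and 6. Rpph1 also missed the threshold without saline replicates 4, 5 or 6 (edgeR adjusted p = 0.0544, 0.0524 and 0.0555) and Cds2 without any saline library but replicate 7 (edgeR adjusted p between 0.0568 and 0.101). DESeq2 called 2 genes, none of them among the 11, limma-voom called 0, and at unadjusted p under 0.05 edgeR had 932. Rapid immediate early genes, which are transcribed within minutes of neuronal activity, had 14 of 16 members above 0 with a median of 0.35 (limma camera adjusted p = 0.000364). Glucocorticoid-responsive genes had 14 of 17 above 0 with a median of 0.15 (limma camera adjusted p = 0.000873, and adjusted p = 0.451 with an estimated correlation), and interferon and inflammatory genes 21 of 22 below 0 with a median of -0.49 (limma camera adjusted p = 2.52e-05). The immediate early and interferon calls were lost likewise (adjusted p = 0.848 with an estimated correlation for both). The interferon score was -1.68 in cocaine replicate 1 and -0.904 in replicate 7 and lay between -0.475 and 0.885 in the other cocaine libraries. Without 4 libraries, these 2 among them, the interferon call was lost at the preset correlation (limma camera adjusted p = 0.463). As these 2 had the lowest scores of the cocaine group, that loss followed from the choice of libraries and does not test the call. The interferon median was -0.22 and -0.30 without saline replicates 1 and 4, while that of glucocorticoid-responsive genes was 0.092 without saline replicate 3. Adjusted over the list alone 2 glucocorticoid-responsive genes passed, and 0 members of these 3 lists passed over all genes.

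From day 1 to day 40 of withdrawal after cocaine, D1 libraries differed in genes of several kinds. Cbx7, a Polycomb protein gene, rose from 80.9 ± 5.06 to 97.9 ± 6.05 CPM (SD, n = 8 each). Hspa5, the endoplasmic reticulum chaperone BiP, rose from 476 ± 54.0 to 649 ± 55 CPM, and Hspa8, a cytosolic chaperone, from 1389 ± 60.4 to 1714 ± 99.0 CPM. The clock output genes Ciart and Dbp fell, from 27.3 ± 2.53 to 13.95 ± 3.83 CPM and from 538.5 ± 50.8 to 410.2 ± 50.2 CPM. For each of these 5 genes all 8 day 40 libraries lay beyond all 8 day 1 libraries. Mx1, an antiviral interferon-induced GTPase, fell from 9.01 ± 7.97 to 0.651 ± 0.632 CPM, and complement C3 from 54.97 ± 31.7 to 9.32 ± 5.27 CPM.

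**Figure D2:**
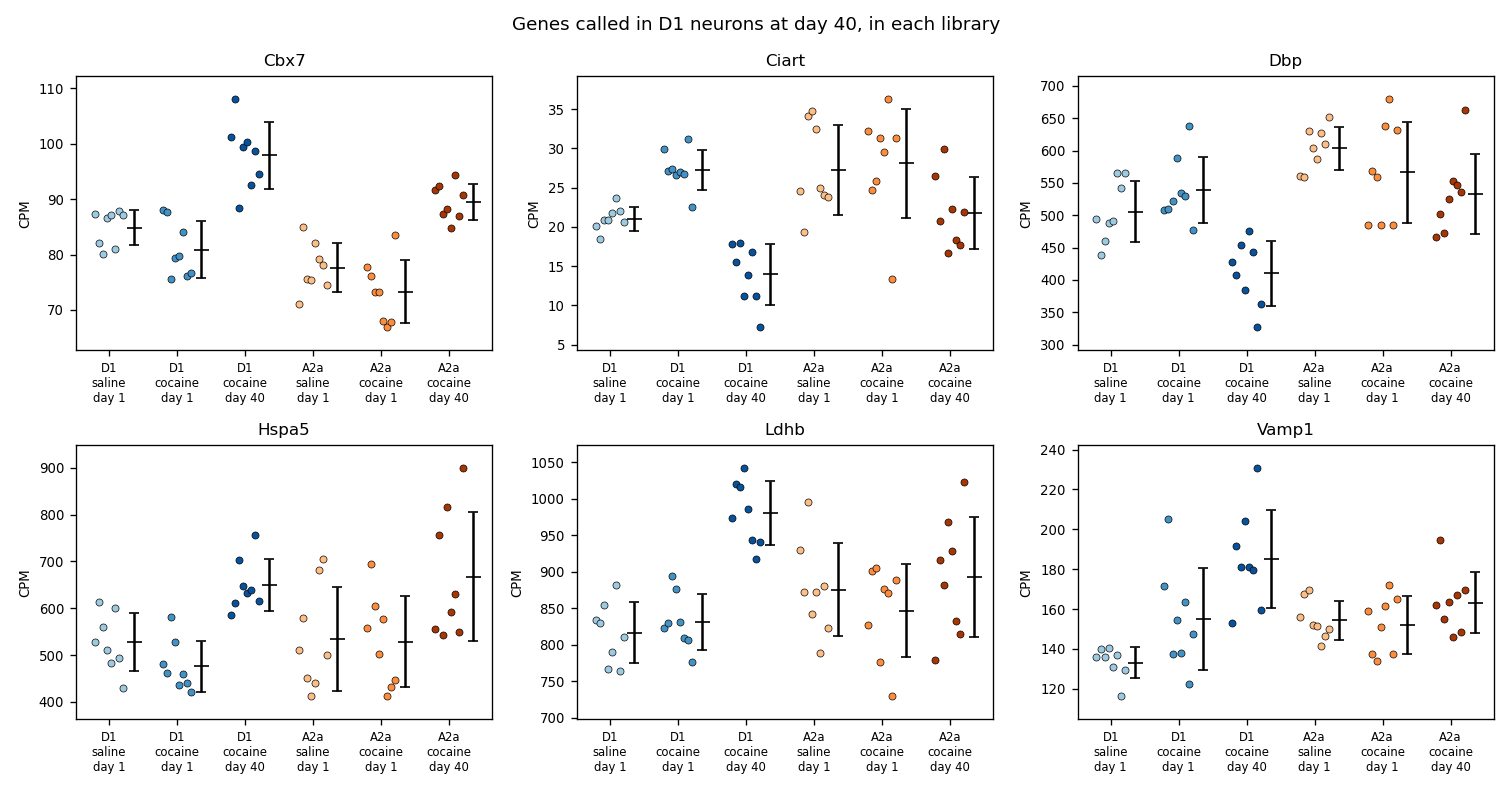
CPM of genes called in D1 neurons at day 40, in each of the 48 libraries by group, with 1 point per library, a tick at each group mean and bars of SD on the linear panels. Ciart averaged 13.95 CPM in D1 day 40 libraries and 27.3 CPM in D1 cocaine day 1 libraries.

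In this contrast edgeR called 289 genes, 109 higher and 180 lower at day 40. Cbx7 differed by 0.28 ± 0.04 (SE), Cntfr, a ciliary neurotrophic factor receptor gene, by 0.33 ± 0.06, Prrt2, a presynaptic protein gene, by 0.30 ± 0.06, and the lactate dehydrogenase subunit gene Ldhb by 0.24 ± 0.05 (edgeR adjusted p = 0.000277, 0.00271, 0.00294 and 0.00672). Slc4a11, a borate and proton transporter family gene, differed by 0.64 ± 0.12, with 7 of 8 day 40 libraries above all of day 1 (edgeR adjusted p = 0.00295). Among the falls, Ciart differed by -0.97 ± 0.14, Dbp by -0.39 ± 0.07, Pabpc1, a poly(A)-binding protein gene, by -0.36 ± 0.07, and Rgs12, a regulator of G-protein signalling, by -0.48 ± 0.10 (edgeR adjusted p = 0.000216, 0.0033, 0.0033 and 0.00649). The largest falls among well-expressed named genes were those of Mx1 (-3.81 ± 0.76), Jchain, the immunoglobulin joining chain (-3.23 ± 0.71), the interferon-induced genes Usp18 and Ifi27l2b (-3.22 and -2.74), Plac8 (-2.83) and C3 (-2.57 ± 0.50), with edgeR adjusted p between 0.00468 and 0.0137. Grik5, a kainate receptor subunit gene (-0.28 ± 0.07), and Gng7, a G-protein gamma subunit gene of the striatum (-0.35 ± 0.08), also fell (edgeR adjusted p = 0.0181 and 0.0171). Fos (0.31), Arc (0.16), Drd1 (-0.063), Pdyn (-0.089) and Gria1 (-0.079) did not pass.

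By list, unfolded protein response genes rose, with 5 of 20 called (9 adjusted over the list alone), among them Hspa5 (0.45 ± 0.11) and Pdia6, a protein disulfide isomerase gene (0.30 ± 0.07), and a median of 0.15 (limma camera adjusted p = 7.18e-07, and adjusted p = 0.205 with an estimated correlation). Heat shock genes rose, with Hspa8 called (4 adjusted over the list alone), 12 of 14 above 0 and a median of 0.14 (limma camera adjusted p = 0.000122, and adjusted p = 0.389 with an estimated correlation). Glycolysis genes rose, with 1 of 18 called (3 adjusted over the list alone), 16 above 0 and a median of 0.10 (limma camera adjusted p = 7.55e-05, and adjusted p = 0.26 with an estimated correlation). Circadian clock genes fell, with 3 of 16 called (6 adjusted over the list alone), namely Ciart, Dbp and Nr1d1 (-0.30 ± 0.07), and a median of -0.13 (limma camera adjusted p = 0.000108, and adjusted p = 0.205 with an estimated correlation). Actin and spine genes fell, with 0 of 25 called (0 adjusted over the list alone) and 21 below 0 (limma camera adjusted p = 0.00177, and adjusted p = 0.26 with an estimated correlation).

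Interferon and inflammatory genes fell, with 11 of 22 called (20 adjusted over the list alone), all 22 below 0 and a median of -1.90 (limma camera adjusted p = 2.77e-16, and adjusted p = 0.205 with an estimated correlation). Microglia markers fell, with 2 of 11 called (8 adjusted over the list alone), among them the integrin gene Itgam (-1.38 ± 0.30), and a median of -0.61 (limma camera adjusted p = 0.000108, and adjusted p = 0.608 with an estimated correlation). These transcripts were also low in D1 day 1 replicates 1 and 2, where C3 read 6.23 and 11.0 CPM. With the interferon list score as a covariate, chosen after the data had been seen, 130 genes were called, 64 of them among the 289, and Hspa5 and Hspa8 did not pass (0.39 ± 0.13 and 0.28 ± 0.09). Models of only the groups compared called 136 genes, DESeq2 524 and limma-voom 543. Without 1 library the count was 191 and 170 (D1 day 40 replicates 4 and 7) or 179, 157, 161 and 171 (D1 day 1 replicates 4, 6, 7 and 8), and Hspa5, Nr1d1 and Grik5 did not pass without day 40 replicate 7 (edgeR adjusted p = 0.0516, 0.0577 and 0.0504).

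**Figure D3:**
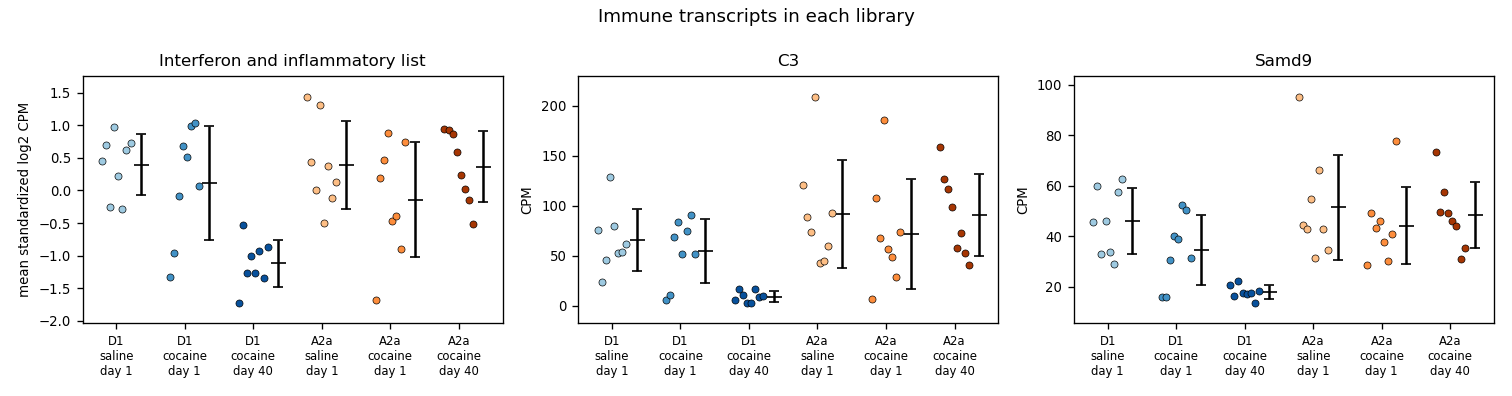
Score of the interferon and inflammatory gene list and CPM of C3 and Samd9 in each of the 48 libraries, by group, with 1 point per library and a tick at each group mean. C3 averaged 9.32 CPM in D1 day 40 libraries and 65.5 CPM in D1 saline libraries, and 2 D1 day 1 libraries lay among the lowest.

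Against D1 saline libraries of day 1, D1 libraries of cocaine day 40 differed in single genes of several kinds. Vamp1, a synaptic vesicle fusion protein gene, rose from 133 ± 7.90 to 185 ± 24.6 CPM (SD, n = 8 each), and Ldhb rose from 816 ± 41.6 to 980.0 ± 44.1 CPM. Hapln4, which links perineuronal matrix proteins to hyaluronan, rose from 15.3 ± 4.40 to 31.8 ± 15.8 CPM. Jchain fell from 25.6 ± 23.2 to 1.20 ± 0.181 CPM, C3 from 65.5 ± 31.1 to 9.32 ± 5.27 CPM, and Samd9, an interferon-responsive gene, from 46.1 ± 13.1 to 18.0 ± 2.69 CPM. The groups differed in both drug and day, since no saline animals were taken at day 40.

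Here edgeR called 406 genes, 167 higher and 239 lower after 40 days. Vamp1 differed by 0.48 ± 0.07 (SE), Tstd3 by 0.37 ± 0.06, Fbxo2, a ubiquitin ligase subunit gene of neurons, by 0.51 ± 0.09, Cygb, the cytoglobin gene, by 0.59 ± 0.11, and Hapln4 by 1.05 ± 0.23 (edgeR adjusted p = 0.000212, 0.000613, 0.000769, 0.00154 and 0.00737). Kcnc1, a potassium channel gene of fast-firing neurons, rose by 0.58 ± 0.14 (edgeR adjusted p = 0.0161), but did not pass without day 40 replicate 7 (edgeR adjusted p = 0.0671). The largest rises among well-expressed named genes also included Coro6, a coronin-family gene (0.88 ± 0.19, and 0.53 without day 40 replicate 8), and Retsat, a retinol saturase gene (0.86 ± 0.18). Among the falls, Jchain differed by -4.41 ± 0.73, Mx1 by -4.06 ± 0.77, C3 by -2.82 ± 0.50, RT1-Ba, a class II histocompatibility gene of uncertain count, by -2.84 ± 0.67, and Tead3, a Hippo pathway transcription factor gene, by -1.77 ± 0.29 (edgeR adjusted p = 0.000552, 0.00209, 0.00117, 0.0141 and 0.000444). The clock genes Ciart (-0.59 ± 0.14) and Dbp (-0.30 ± 0.07) fell as well, and Rpl10a, a ribosomal protein gene with near-identical copies, fell from 926 ± 165 to 542 ± 66.9 CPM (edgeR adjusted p = 0.0161, 0.0164 and 0.00154).

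Respiratory chain genes of the nucleus rose in this contrast, with 69 of 70 above 0, 3 called (15 adjusted over the list alone) and a median of 0.14 (limma camera adjusted p = 2.05e-16, and adjusted p = 0.367 with an estimated correlation). Ndufs7, a complex I subunit gene, rose from 253 ± 17.3 to 305 ± 17.5 CPM. All 18 glycolysis genes were above 0, with 3 called (10 adjusted over the list alone), namely Ldhb (0.26 ± 0.05), Pgam1 (0.19 ± 0.04) and Pgk1 (0.22 ± 0.05), and the list rose with a median of 0.13 (limma camera adjusted p = 6.55e-07, and adjusted p = 0.246 with an estimated correlation). Heat shock genes rose with 14 of 14 above 0, 0 called and 3 adjusted over the list alone (limma camera adjusted p = 0.000329, and adjusted p = 0.367 with an estimated correlation). Unfolded protein response genes rose with 1 called and 5 adjusted over the list alone (median 0.10, limma camera adjusted p = 0.00116, and adjusted p = 0.466 with an estimated correlation). Circadian clock genes fell, with 2 called and 6 adjusted over the list alone (limma camera adjusted p = 0.00197, and adjusted p = 0.367 with an estimated correlation).

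Interferon and inflammatory genes fell, with 14 of 22 called (21 adjusted over the list alone) and a median of -1.93 (limma camera adjusted p = 1.35e-21, and adjusted p = 0.243 with an estimated correlation). Microglia markers fell, with 3 of 11 called (7 adjusted over the list alone), among them Itgam (-1.23 ± 0.30), and a median of -0.78 (limma camera adjusted p = 4.93e-05, and adjusted p = 0.467 with an estimated correlation), while astrocyte markers had a median of 0.22 and oligodendrocyte markers -0.096. With the interferon list score as a covariate, chosen after the data had been seen, edgeR called 82 genes, and Kcnc1 (0.42 ± 0.17), Hapln4 (0.96 ± 0.28), Ciart (-0.58 ± 0.18) and Dbp (-0.30 ± 0.09) did not pass, while Vamp1, Tstd3, Fbxo2 and Ldhb still passed. That score did not overlap between the groups, at -1.72 to -0.53 in D1 day 40 and -0.28 to 0.98 in D1 saline libraries, and the errors of these 4 genes were larger with it. Under that covariate the microglia list passed in the upward direction. Limma-voom called 1034 genes and DESeq2 639, and without D1 day 40 replicate 4 or D1 saline replicate 8 edgeR called 266 and 270. Without day 40 replicate 7, Dbp did not pass (edgeR adjusted p = 0.051).

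In A2a libraries, cocaine day 40 against cocaine day 1, Cbx7 rose from 73.3 ± 5.76 to 89.6 ± 3.23 CPM (SD, n = 8 each). Tnk2, a non-receptor tyrosine kinase gene, rose from 183 ± 10.1 to 233 ± 18.7 CPM, and ND4, a mitochondrially encoded complex I subunit gene, from 31.3 ± 2.41 to 60.0 ± 9.50 CPM. Lyrm7, a complex III assembly factor gene, fell from 43.9 ± 3.46 to 36.3 ± 3.16 CPM. All 8 day 40 libraries lay beyond all 8 day 1 libraries for each of these 4 genes. Fos stood at 13.4 ± 9.25 and 16.1 ± 7.23 CPM, a difference that did not pass (edgeR adjusted p = 0.837).

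This contrast had 41 called genes in edgeR, 17 higher and 24 lower at day 40, and 23 of them had a name. Log2 differences were 0.29 ± 0.04 for Cbx7, 0.35 ± 0.06 for Tnk2, 0.94 ± 0.20 for ND4, -0.27 ± 0.05 for Lyrm7 and -0.22 ± 0.04 for Mtch2, a mitochondrial outer membrane protein gene (SE, edgeR adjusted p = 0.000645, 0.000733, 0.0192, 0.00748 and 0.00642). The protease gene Capn1 (0.78 ± 0.15), the Patched-family gene Disp3 (0.82 ± 0.17), Cys1 (0.50 ± 0.11), the Ras GTPase-activating gene Rasa3 (0.42 ± 0.09) and Irag2 (0.38 ± 0.09) rose too. ND4 did not pass without day 40 replicate 1 (edgeR adjusted p = 0.0566), and none of the 12 other mitochondrially encoded protein genes passed (median log2 difference 0.01, from -0.78 to 0.12). ND5, another complex I subunit gene, stood at 1145 and 1222 CPM, far above ND4. Rasa3 did not pass without day 40 replicate 1 or 3 (0.40 and 0.36), Cys1 without day 40 replicate 4 or 8 or day 1 replicate 4 (0.44, 0.45 and 0.43), and Irag2 without day 40 replicates 1, 3 or 4 or day 1 replicates 1, 5, 6 or 7 (0.34 to 0.37).

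Of the lists, unfolded protein response genes rose, with 0 of 20 called (6 adjusted over the list alone), 17 above 0 and a median of 0.13 (limma camera adjusted p = 0.000121, and adjusted p = 0.957 with an estimated correlation). Interferon and inflammatory genes rose, with 19 of 22 above 0 and a median of 0.48 (limma camera adjusted p = 0.000562, and adjusted p = 0.957 with an estimated correlation), and microglia markers rose with all 11 above 0 and a median of 0.19 (limma camera adjusted p = 0.02, and adjusted p = 0.957 with an estimated correlation). These immune transcripts were low in A2a day 1 replicate 1, where C3 read 6.41 CPM. Without that library the interferon and microglia calls were lost (medians 0.32 and 0.07, limma camera adjusted p = 0.0678 and 0.216). The microglia call was lost as well without day 40 replicates 1, 2 or 6 or day 1 replicate 7 (limma camera adjusted p = 0.0503, 0.113, 0.058 and 0.176; medians 0.104, 0.106, 0.168 and 0.096), and its median was 0.279 and 0.359 without day 40 replicate 8 and day 1 replicate 4. The interferon median was 0.258 without day 40 replicate 1. The count of 41 was 65 and 69 without A2a day 1 replicates 2 and 8, 71 in DESeq2, 20 in limma-voom and 5 in a model of only the groups compared. It was 9 with a term for the processing order.

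Between A2a libraries of cocaine day 40 and of saline day 1, no gene passed in edgeR. The groups differed in drug, day and description number, which cannot be told apart. Immediate early genes had higher means after cocaine: Fos stood at 16.1 ± 7.23 against 7.22 ± 2.68 CPM (SD, n = 8 each), Fosb at 44.7 ± 14.7 against 28.9 ± 5.95 CPM and Arc at 114 ± 42.2 against 64.2 ± 16.2 CPM. Their log2 differences were 1.16 ± 0.32, 0.63 ± 0.16 and 0.83 ± 0.26 (SE, edgeR adjusted p = 0.468, 0.356 and 0.572). Cbx7 was at 89.6 ± 3.23 against 77.6 ± 4.42 CPM and Nfil3, a transcription factor gene of the clock and immune systems, at 16.3 ± 1.77 against 12.1 ± 1.13 CPM, with 7 of 8 cocaine libraries above every saline library for each (edgeR adjusted p = 0.141 and 0.248). Lyrm7 (-0.25 ± 0.05) had a lower mean without passing (edgeR adjusted p = 0.141).

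**Figure D4:**
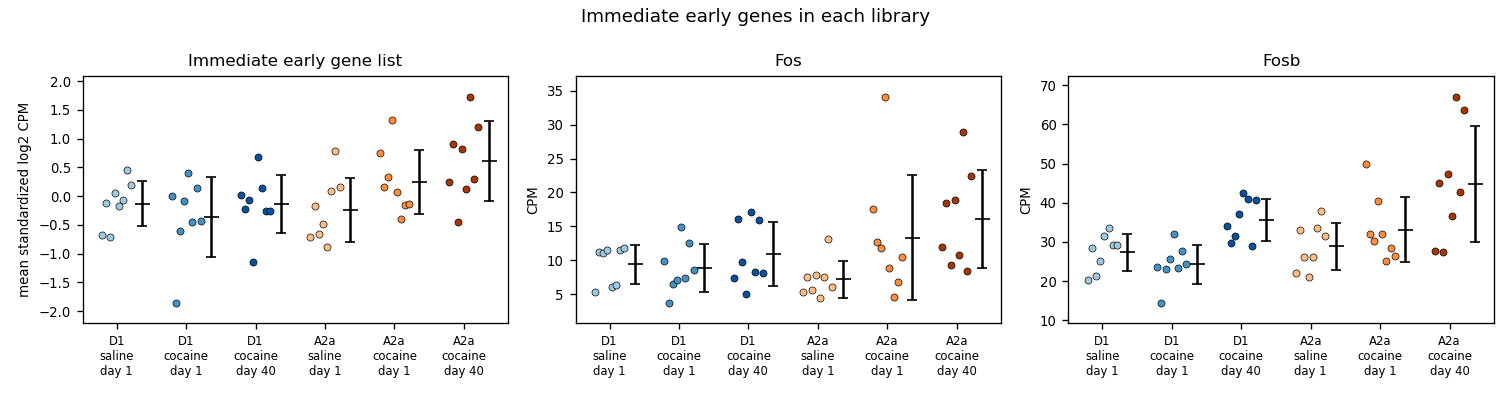
Score of the rapid immediate early gene list and CPM of Fos and Fosb in each of the 48 libraries, by group, with 1 point per library and a tick at each group mean. Fos averaged 16.1 CPM in A2a day 40 libraries, 13.4 CPM in A2a cocaine day 1 libraries and 7.22 CPM in A2a saline libraries.

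As a list, rapid immediate early genes rose, with all 16 above 0, 0 called over all genes, 8 adjusted over the list alone and a median of 0.49 (limma camera adjusted p = 8.67e-11, and adjusted p = 0.314 with an estimated correlation). Unfolded protein response genes rose with 19 of 20 above 0 and a median of 0.14 (limma camera adjusted p = 2.29e-07, and adjusted p = 0.314 with an estimated correlation), and heat shock genes with 13 of 14 above 0 and a median of 0.15, or 0.099 without day 40 replicate 8 (limma camera adjusted p = 3.61e-06, and adjusted p = 0.327 with an estimated correlation). Adjusted over the list alone 0 and 2 of their members passed, and 0 over all genes. The count over all genes was 0 by edgeR (838 at unadjusted p under 0.05), 4 by DESeq2 and 0 by limma-voom. It was 1 without A2a saline replicate 7.

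Whether cocaine at day 1 acted differently on the neuron types was tested as an interaction, the change in D1 minus the change in A2a. One gene without a name, ENSRNOG00000047746, passed in edgeR (-12.5 ± 2.24 on the log2 scale, SE, adjusted p = 0.0228). Stag1, a cohesin subunit gene, differed by -0.50 ± 0.12 without passing (edgeR adjusted p = 0.372). Rapid immediate early genes had a median interaction of -0.41 (limma camera adjusted p = 8.91e-05, and adjusted p = 0.945 with an estimated correlation). The count was 0 without any one of D1 cocaine replicates 1, 2, 3, 5, 7 and 8, A2a cocaine replicate 7, D1 saline replicate 5 and A2a saline replicates 1, 2, 3, 5, 6, 7 and 8, and 2 without any other A2a cocaine library. DESeq2 and limma-voom called 0, and 522 genes lay at unadjusted p under 0.05 in edgeR.

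The interaction of neuron type with withdrawal day had 10 called genes, 3 positive and 7 negative (edgeR). Zc3hav1, the zinc-finger antiviral protein gene (-2.21 ± 0.42), and Xaf1, an interferon-induced apoptosis gene (-1.32 ± 0.26), were more negative in D1 than in A2a neurons, as was Wdtc1 (-0.34 ± 0.07), with edgeR adjusted p of 0.0163, 0.0163 and 0.0409. Interferon and inflammatory genes had a median of -2.25, with 20 of 22 negative members past 0.05 adjusted over the list alone (limma camera adjusted p = 2.34e-21, and adjusted p = 0.254 with an estimated correlation). Microglia markers had a median of -0.97 and respiratory chain genes of the nucleus 0.12 (limma camera adjusted p = 2.84e-07 and 4.00e-09, and adjusted p = 0.943 with an estimated correlation for both). Upper-quartile scaling gave 20 called genes, 3 positive and 17 negative. With the order block edgeR called 2 genes, 1 of them among the 10, and with surrogate variables 3, of which 2 were shared. Zc3hav1, Xaf1 and Wdtc1 then missed the threshold at -2.24, -1.29 and -0.31 (edgeR adjusted p = 0.0519, 0.0519 and 0.0788 with the order block).

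This interaction count moved with single libraries. It was 6 without D1 day 40 replicate 4, A2a day 40 replicate 1 or 6, or D1 day 1 replicate 6, 7 or 8, and 39 without A2a day 40 replicate 8. It was 70 and 74 without D1 day 1 replicates 1 and 2, and 68 and 29 without A2a day 1 replicates 4 and 8. Wdtc1 did not pass without D1 day 40 replicates 3, 4, 5 or 7, A2a day 40 replicates 1, 2, 4 or 6, D1 day 1 replicates 4, 6, 7 or 8, or A2a day 1 replicates 1, 3, 5 or 6 (-0.35 to -0.32). DESeq2 called 25 positive and 98 negative genes, and with the interferon list score as a covariate, or in a model of only the groups compared, edgeR called 0.

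The comparisons of day 1 and of day 40 with saline shared their control libraries, so their overlap was counted. In D1 neurons edgeR called 0 genes at day 1 and 406 at day 40, and in A2a neurons 11 and 0. With an empty list on one side in each neuron type, the overlap was 0 by necessity, with the controls shared or split into 4 and 4, and does not bear on shared changes.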

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

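The tests of the interferon pattern and the marker test without D1 day 40 replicate 7 were chosen only after those results were seen. So were the permutation at day 1 and the list tests with 1 library left out. For the other tests of the fast-spiking and immediate early patterns and for the divisions, the criteria were written down before their outcomes were known. The fast-spiking and immediate early patterns themselves had been seen by then. Interferon and microglial transcripts were low in the D1 libraries of day 40. There the interferon list had a median log2 difference of -1.93 from saline and of -2.25 in the interaction of neuron type and withdrawal day. A like fall was not seen in A2a libraries, where the same list had a median of 0.483 from day 1 to day 40, or 0.258 without A2a day 40 replicate 1. The interaction had a limma camera p of 0.00529 with an estimated correlation (adjusted p = 0.254). The A2a rise lost its call without day 1 replicate 1. As the day 40 libraries of each neuron type carried a description number of their own, unlike effects of withdrawal cannot be told apart from unlike animal sets. The tables argue against a lower share of every other cell type, because astrocyte, oligodendrocyte and endothelial and mural markers had medians of 0.216, -0.096 and -0.152. Microglia markers had -0.78, so a lower share of microglia or other immune cells alone is not covered by that test and stays open. An animal set or processing round shared by the D1 day 40 libraries stays open too. It cannot be told apart from the group, as 0 other libraries carried their description number 85. A change in D1 neurons at cocaine day 40 stays open as well and was not tested. A low score by itself needed neither day 40 nor D1 neurons. D1 cocaine day 1 replicates 1 and 2 and A2a cocaine day 1 replicates 1 and 7 lay within the D1 day 40 range of -1.72 to -0.532. Of the day 1 libraries, the 4 with the lowest interferon scores carried the description numbers 89 (-1.68, -1.32 and -0.968) and 92 (-0.904, A2a cocaine replicate 7). The number 89 was carried by 15 libraries of day 1 in all. No saline library lay within the D1 day 40 range, the lowest being -0.494 in A2a saline.

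Kcnc1, Hapln4 and Vamp1, single genes known from fast-firing neurons, were high in the D1 libraries of day 40, but Kcnc1 did not pass without replicate 7 (0.442). With the interferon covariate Kcnc1 (0.417 ± 0.17) and Hapln4 (0.961 ± 0.28) lost their calls, but its score parts the groups without overlap and widens the errors, so for Hapln4, at 1.05 ± 0.23 before, this does not weigh against the pattern. A candidate explanation is RNA of parvalbumin interneurons or of the neighbouring pallidum: 10 of 10 tested markers written down before this test had positive log2 differences from saline with a median of 0.289 (limma camera p = 0.0154 with an estimated correlation), or of 0.223 without replicate 7 (p = 0.0342), whose score of medium spiny neuron markers was -3.29 against -1.18 in the next library. Some markers written down were not tested, and Pvalb, the parvalbumin gene, was not among the 10. The median also fell short of the size set for this source before the test, so the test left it undecided. Nefh, a neurofilament gene, passed (0.52 ± 0.11, edgeR adjusted p = 0.00459), but the most abundant markers, Nefl and Nefm, differed by only 0.063 ± 0.06 (605 against 579 CPM) and 0.16 ± 0.13 (166 against 149 CPM), and medium spiny neurons also express neurofilament genes. With all libraries the median was 0.162 against day 1 (10 of 10 positive) and 0.107 in A2a day 40 against saline (8 of 10). The named source may account for part of the pattern and stays open, as does a change within D1 neurons, which was not tested. Upper-quartile factors moved the median of all genes by only -0.009, which argues against the choice between them and TMM as the source. An error common to both kinds of factor was not tested.

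Rapid immediate early genes were high in A2a cocaine libraries of day 40, a limma camera call that was lost with an estimated correlation (adjusted p = 0.314). One deviating library is argued against, as the lowest list median with any library left out was 0.415, and processing order is argued against by a median of 0.462 with the order block (limma camera p = 0.0136 with an estimated correlation). Of the 6435 divisions of the 16 libraries, 164 gave a mean list median as large as the real 0.497 (two-sided exact permutation p = 0.0255, highest other 0.796). At day 1 the same median of differences in mean log2 CPM, not the model's 0.35, was 0.286 (exact permutation p = 0.0963). The order block and permutation p values were not adjusted over the 48 lists tested, and the list was followed up because of its call. An effect of cocaine on activity genes of A2a neurons and handling of the animals on the last day stay open, since the labels do not state the latter and neither was tested. The day 40 group also differed from saline in withdrawal day and description number, and these cannot be told apart from the drug. Y-linked transcripts were present in 4 of 8 day 40 and 6 of 8 saline libraries.

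For 4 counts of called genes, 100 divisions of the same libraries argue against a random split of these libraries as the source. Each was modelled with only the groups compared, so the counts are not those of the main model. In the day 40 comparisons the divisions cannot tell withdrawal day from an animal set, since each day 40 group carried its own description number. In D1 day 40 against day 1, 1 of 100 divisions, the real one, reached its 136 genes (highest other 2), and in A2a the real 5 genes were reached by 1 of 100 (highest other 1). In D1 day 40 against saline 1 of 100 reached the real 506 (highest other 14), and in D1 against A2a 1 of 100 reached 1415 (highest other 507). For the comparisons whose real count was 0 in such models, all 100 divisions had at least as many by necessity, so the divisions say nothing on chance. The highest other counts there were 639 (D1 day 1 against saline), 162 (A2a day 1 against saline), 13 (A2a day 40 against saline), 1 (interaction with cocaine) and 1 (interaction with day). The divisions with 639 and 507 genes each put all 4 libraries of the first 2 order blocks on one side, and that with 162 put 2 and 7 libraries of number 89 on its sides. What set these divisions apart was not tested. For those with 639 and 507 genes the split of the order blocks was not enough by itself. In each of those 2 comparisons 8 other divisions with that split called 0 genes. With the order block, edgeR called 0 genes in both day 1 comparisons and 1586 in D1 against A2a.

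A single library stood apart from its group, by a gap above Dixon's critical ratio, in 14 of 133 groups of 8. The nominal rate of 1 in 20, or 6.7, is no fair yardstick for this count. Some of the genes were named because of such values, and several flags came from the same library. Totals did so at 5.3 M counts (A2a cocaine day 1 replicate 7) and 55.1 M (A2a day 40 replicate 1). In the shallow library Rpph1 stood at 270.8 and Cds2 at 45.4 CPM. Fos was at 34.1 CPM in A2a cocaine day 1 replicate 4 and at 13.1 CPM in A2a saline replicate 7, and the immediate early score was -1.85 in D1 cocaine day 1 replicate 2. D1 saline replicate 4 held 1918 CPM of the unnamed gene ENSRNOG00000048402, 376 CPM of Cd74 and 6.11 CPM of Mzb1. The others were Mmp9 at 3.52 CPM (D1 saline replicate 2), Mx1 at 2.00 CPM (D1 day 40 replicate 2), Lyrm7 at 29.7 CPM (A2a day 40 replicate 6) and Vamp1 at 116 CPM (D1 saline replicate 7).

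The interactions of neuron type with cocaine and with withdrawal day had a few calls, which ended in models of only the groups compared (0 genes in both). For cocaine at day 1, edgeR called 1 gene, lost in DESeq2, in limma-voom and with the order block, and limma camera called immediate early genes (median -0.41), GABA-A receptor subunits (-0.16) and synaptic adhesion genes (-0.09), each lost with an estimated correlation (adjusted p = 0.945). The latter 2 were also lost without any one of D1 cocaine replicates 4, 5 and 7, A2a cocaine replicates 5 and 7, D1 saline replicates 1, 2, 5, 6 and 7 and A2a saline replicates 1, 2, 3, 4 and 8 (limma camera adjusted p from 0.0524 to 0.548). Their medians were -0.048 and -0.035 without A2a cocaine replicate 7, -0.106 for the first without A2a cocaine replicate 4, and -0.056 and -0.06 for the second without D1 cocaine replicate 7 and D1 saline replicate 2. For withdrawal day, edgeR called 10 genes, among them Zc3hav1 (-2.21), Xaf1 (-1.32) and Wdtc1 (-0.34). The lists called by limma camera were interferon (-2.25), microglia (-0.97), circadian clock (-0.18), choroid plexus and ependymal markers (0.69), respiratory chain (0.12), proteasome (0.091), glycolysis (0.073) and mitochondrial ribosome genes (0.065). With an estimated correlation none passed (adjusted p = 0.254 for interferon and 0.943 for the rest). At the preset correlation limma camera lost the choroid plexus call without A2a day 1 replicate 7 (adjusted p = 0.0529) and the clock call without D1 day 40 replicates 4 or 7, A2a day 40 replicate 8 or A2a day 1 replicate 4 (0.0513, 0.0969, 0.0791 and 0.0612). It lost the glycolysis call without D1 or A2a day 40 replicate 1 or D1 day 1 replicate 8 (0.0515, 0.0713 and 0.0593) and the mitochondrial ribosome call without A2a day 40 replicate 1 (0.068), whose median was 0.101 without A2a day 40 replicate 8.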

How the results depend on the processing

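The settings without 3 or 4 libraries and with an interferon covariate, and the list tests with 1 library left out, were chosen only after the data had been seen. Counts are of genes called by edgeR unless another tool is named, against the main counts of 0 (D1 day 1 against saline), 11 (A2a day 1), 289 (D1 day 40 against day 1), 41 (the same in A2a), 406 (D1 day 40 against saline), 0 (the same in A2a), 1266 (D1 against A2a), 1 (interaction with cocaine) and 10 (interaction with day). With 1 library left out at a time these ranged from 0 to 0, 0 to 17, 157 to 412, 30 to 69, 266 to 548, 0 to 1, 1062 to 1268, 0 to 2 and 6 to 74.

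At an adjusted p of 0.1 the counts were 597 and 124 (day 40 against day 1 in D1 and A2a), 741 (D1 day 40 against saline), 2 and 78 (interactions with cocaine and day). With DESeq2 they were 2 (A2a day 1), 524, 71, 639, 4 (A2a day 40 against saline), 0 and 1.2e+02 (25 positive and 98 negative) in the interactions. With limma-voom they were 0 (A2a day 1), 543, 20, 1034 and 0 (interaction with cocaine). No low-count filter gave 27 in A2a day 1, and the stricter filter 2 there, 0 and 18 in the interactions. Upper-quartile factors gave 20 in the interaction with day. Models of only the groups compared gave 0 (A2a day 1), 136 (D1), 5 (A2a), 0 and 0 (interactions), and models of one cell type 1 (A2a day 1) and 5 (A2a day 40 against day 1). Surrogate variables gave 0 (A2a day 1), 551, 136, 743, 11, 1913, 0 and 3, and the score of non-neuronal markers 63 (A2a) and 649 (D1 day 40 against saline). The processing order term gave 0 (A2a day 1), 9 (A2a day 40 against day 1), 0 and 2 (interactions), and the term for the middle description number 0 (A2a day 1) and 0 (interaction with cocaine). Without 3 libraries the counts were 586 (D1 day 40 against day 1), 1 (A2a day 40 against saline), 0 and 131 (interactions). Without 4 libraries they were 0 (A2a day 1), 660, 19, 676, 1, 0 and 101. The 3 were picked for low immune transcripts, so counts that include such transcripts partly follow from that choice. The interferon covariate gave 0 (A2a day 1), 130, 18, 82, 0 and 0. Apart from the settings that hold fewer libraries or genes, the cause was not tested.

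With the replicate number as a block, the counts were 0 (A2a day 1), 314 and 24 (day 40 against day 1), 484 (D1 day 40 against saline), 1329 (D1 against A2a), 0 and 8 (interactions). The labels do not pair the samples by these numbers, and libraries of 1 number were weakly alike. The score of sex-linked transcripts was above 0 for replicates 1 to 4 of every group. It was below 0 for replicates 5 to 8 of the D1 groups and of A2a day 40, so the block partly follows these transcripts. Whether this made the libraries alike was not tested. The mean correlation of deviations was 0.045 for same-numbered libraries and -0.006 for others, 28 of 120 same-numbered pairs lay above 0.1, and a library's best match had its own number in 63 of 240 cases, where chance would give 30.

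Of 243 named-gene results, the changes reversed for these, with the cause not tested. Rpph1 in A2a day 1 was -0.11 in DESeq2, -0.36 in limma-voom, -0.031 with surrogate variables, -0.038 without 4 libraries and -0.12 without A2a day 1 replicate 7. Rpph1 in A2a day 40 against day 1 was 0.041 in DESeq2, 0.078 with surrogate variables and 0.041 without A2a day 1 replicate 7. With any other library left out both kept their signs, at the most 5.95 (without A2a day 1 replicate 4) and -6.07 (without A2a day 40 replicate 4). With the interferon covariate Psmb8 and Psmb9, immunoproteasome genes, were 0.19 and 0.11 (D1 day 40 against day 1) and 0.083 and 0.017 (against saline), C1qa was 0.007, and the microglia list turned upward (D1 day 40 against saline, limma camera adjusted p = 0.0131). The interferon covariate ended 75 calls of named genes, models of only the groups compared 35 and models of one cell type 24. Of 72 list calls, 32 were lost without some single library, and 0 passed in the other direction. The median of 1 list changed sign: interferon genes in D1 day 1 (-0.091) stood at 0.054, 0.04 and 0.025 without cocaine replicates 1 and 2 and saline replicate 4. The scaling factors moved the median of all genes by at most 0.016 on the log2 scale. The shallow library of 5.3 M counts limits genes of low level in A2a day 1 comparisons, which were not simulated. In the simulated D1 day 40 against saline contrast, 1.5-fold changes of genes with a mean above 1 CPM were recovered in 71.6% of cases.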

Other observations

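The genes in this part were chosen after their values were seen, and the test of Rpl10a against the interferon score was planned before its result was known. Mzb1, a plasma cell chaperone gene, averaged 0.125 ± 0.12 CPM at day 40 and 1.80 ± 1.87 CPM after saline in D1 libraries (SD, n = 8 each), with 6.11 CPM in saline replicate 4, a log2 difference of -3.83 ± 0.84 (SE, edgeR adjusted p = 0.00757, and -3.22 without that library). Cd74, the invariant chain of class II histocompatibility molecules, averaged 20.2 ± 14.8 and 128 ± 109 CPM (-2.68 ± 0.66, edgeR adjusted p = 0.0164), and did not pass without saline replicate 4 (-2.21, edgeR adjusted p = 0.0543). The gene with the smallest p in this contrast, ENSRNOG00000048402, has no name in the deposited table. It averaged 573 ± 584 CPM in D1 saline libraries, lay between 0 and 822 CPM in D1 cocaine day 1 libraries and at most at 0.174 CPM in D1 day 40 libraries, while A2a libraries ranged from 5.35 to 539 CPM after saline, from 1.00 to 2926 CPM at cocaine day 1 and from 243 to 1571 CPM at day 40.

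In D1 neurons at day 40 against saline, tubulin genes rose as a list, with 2 called and 4 adjusted over the list alone (median 0.08, limma camera adjusted p = 0.0354, and adjusted p = 0.367 with an estimated correlation), a call lost without day 40 replicates 1, 6 or 7 or saline replicates 1 or 6 (limma camera adjusted p = 0.0575, 0.0571, 0.0997, 0.0561 and 0.0669). In A2a neurons at day 40 against saline, 57 of 69 ribosomal protein genes were above 0 with a median of 0.08 (limma camera adjusted p = 1.40e-06, and adjusted p = 0.993 with an estimated correlation). That median was 0.124, 0.038 and 0.053 without saline replicates 3, 6 and 7.

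Rpl10a, whose product is the ribosomal protein commonly tagged for ribosome pull-down, averaged 926 ± 165 CPM in D1 saline, 831 ± 298 in D1 cocaine day 1 and 542 ± 66.9 in D1 day 40 libraries (SD, n = 8 each). In A2a libraries it averaged 454 ± 65.5, 514 ± 64.0 and 514 ± 59.5 CPM. The labels do not name the tagged protein, near-identical copies make the count uncertain, and the interaction with day did not pass (-0.62, edgeR adjusted p = 0.205). A hypothesis that Rpl10a and the immune transcripts may vary together between animals was tested as deviations from group means in the 40 libraries outside D1 day 40, the only relation computed. Pearson's r was 0.277 (permutation p = 0.147) and Spearman's rho 0.152 (permutation p = 0.382). Without the 2 farthest libraries r was 0.112, and by description number it was -0.379 (88, 8 libraries), 0.333 (89, 15 libraries), 0.149 (91, 8 libraries) and 0.372 (92, 9 libraries). The question stays open.

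Transcripts of 4 Y-linked genes were all above 1 CPM in 4 of 8 libraries of 5 groups and in 6 of 8 A2a saline libraries. The labels do not give the sex of each animal, and sex was neither inferred nor modelled. The A2a saline group is the control of both A2a comparisons with saline and 1 side of the D1 against A2a comparison.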
